A study of Mus musculus with 17 samples.

How the data were processed

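RNA was sequenced from mouse embryonic fibroblasts (MEFs) that carried 2, 1 or 0 intact alleles of Usp28, written +/+, +/− and −/− as the labels give them. Usp28 encodes a deubiquitinase, an enzyme that removes ubiquitin from other proteins. The cells came from C57BL/6 embryos of day 13.5 and were immortalized with a retrovirus that carries a short hairpin RNA against p19ARF, per the labels. The immortalized set has 3 libraries for each of the 3 genotypes. The Ras set has 2 libraries in each of 4 groups, in cells that also received activated HRas together with a GFP vector or, in 1 group of +/+ cells, a vector for USP28. RNA was selected for poly(A) tails, prepared with either of 2 NEBNext kits and sequenced on an Illumina Genome Analyzer IIx, per the labels' protocols. The labels do not say which library was made with which kit, so a kit effect could not be examined.

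The authors deposited 1 table for each set, and both hold comparisons against +/+ with no values for single libraries. Per the submitters' processing notes, reads went through CASAVA and FastQC, were aligned to mm9 with Bowtie 0.12.8 and were compared by the authors with edgeR. Per the file headers, each comparison gives a log2 concentration (the mean over both groups of a gene's log2 share of the reads), a log2 ratio of +/+ over the other group, and a p-value. The Ras table also gives p-values adjusted by the authors. Deposited log2 ratios were turned to the other group over +/+ throughout. Only the direction in the headers makes the +/+ levels match between the comparisons of 1 table: their median log2 difference was then 0.00 for the immortalized set, against 0.27 with the ratio turned. The immortalized table holds 37576 distinct gene IDs after 35 repeated lines were dropped, and 86.9% of the IDs have a symbol in the annotation used here. The Ras table holds 33440 distinct gene IDs after 24 repeats, and 97.6% have a symbol.

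Group levels in RPM (a gene's reads scaled to a depth of 1000000) were rebuilt from the deposited log2 concentration and log2 ratio. Low values lie on steps of 1 read, which gives the depth summed over the libraries of a group. It was 12.3 M reads (M, 1000000) for immortalized +/+, 12.4 M for +/− and 11.4 M for −/−. In the Ras set it was 11.4 M for +/+, 13.2 M for +/−, 13.95 M for −/− and 13.4 M with USP28. With these depths, 79.6% to 100% of the values under 20 reads lay within 0.1 of a whole number, depending on the group. A single read is 0.0717 to 0.0878 RPM. Where a group had 0 reads, the fold is given as a bound against 3 reads summed over that group, and where it had 1 to 3 reads the ratio is given with a 95% interval for counting error alone. Counting intervals and floors cover counting error only. The 95% interval given for Usp28 in Ras −/− instead rests on the implied standard error described next. The wildtype levels of the 2 tables differed by a median of 0.60 on the log2 scale, so levels were not tested between the tables. Where levels of both sets stand side by side, they are to be read within a set.

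The deposited p depended on level and fold alone, which means that a single dispersion was used for all genes of a comparison. It was fitted here to the deposited p and corresponds to a coefficient of variation between libraries of 21.1% for immortalized −/−, 32.3% for immortalized +/−, 14.4% for Ras −/−, 14.2% for Ras +/− and 12.6% for USP28 overexpression. Across genes, z values rebuilt from this dispersion correlated with the deposited z at r of 0.998 to 0.999. The standard errors given beside folds are implied by this dispersion and the read counts, and are not a spread measured for the gene. Genes that vary between cultures more than the typical gene therefore have errors that are too small.

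The design written before the data were examined foresaw a description only, should the tables hold comparisons alone, and the tests on them were chosen after the tables were seen, except a test for calls near Usp28 that was planned before. Genes with a mean level of at least 1 RPM were tested, the deposited p was adjusted over them by Benjamini and Hochberg's method, and genes with an adjusted p under 0.05 are called changed. Differences between 2 comparisons (−/− against +/−, and the genotype effect in the Ras set minus that in the immortalized set) were tested with an approximate Wald test on the difference of the log2 ratios, with 0.5 reads added to each group. For −/− against +/− each group was given the dispersions of both comparisons, because the part of the shared +/+ group could not be separated. This makes the error an upper bound at the common dispersion only, and it can still be too small for genes that vary more. Levels of the Ras set against the immortalized set were not tested because the tables were normalized apart. Shared calls were set beside the number that 2 independent lists would share in each direction (n1 × n2 / N) and beside 20 simulations with no effect and a common +/+ group. Covariances of log2 folds were compared with their simulated values because the +/+ libraries could not be split.

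The 26 gene lists of pathways and cell type markers were fixed before the data were examined. Lists with at least 5 tested members were compared with all other tested genes by limma's camera test on signed z values, with a preset correlation of 0.01 and adjustment over the lists of a comparison. A correlation between list members could not be estimated, because no values for single libraries are in the tables, and a preset of 0.05 was run in its place. Members are also counted as called when p is adjusted over the list alone. List medians use folds with 0.5 reads added to each group. The median and the test differed in sign in 20 of the 196 list tests, and none of these 20 was called.

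Named genes follow a rule written before the data were examined. It takes Usp28 and Fbxw7, the 6 called genes with the largest and the 6 with the smallest log2 fold at a mean level of at least 5 RPM, and the transcripts of Myc, Jun, Ccne1 and Notch1. It also takes the member with the smallest p in each of the first 12 lists, with 2 further members where the list is called, and Xist with the Y-linked genes. Unnamed loci, pseudogenes, immunoglobulin and olfactory genes were passed over. The part of the rule that asked for groups whose libraries do not overlap could not be applied. Some genes that the rule takes are not reported here. Other genes are named with the statement that they were chosen after their values were seen. The exception is further members of lists that were not called, which lie outside the rule and carry no such statement.

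Each step was tested on simulated counts with the real levels and depths, the fitted common dispersion of the comparison and 200 altered genes. Genes altered 4-fold were called in 95% of cases for immortalized −/− (16671 genes), 78% for immortalized +/− (16702 genes), 98% for Ras −/− (15461 genes), 95% for Ras +/− (15452 genes) and 99% for USP28 overexpression (15483 genes). For genes altered 2-fold the shares were 52%, 8%, 74%, 75% and 79% in the same order. Between 5 and 10 unaltered genes were called in each of the 5 simulations. Every simulated gene had the common dispersion of its comparison, which the test also uses. These counts therefore leave out false calls from genes that vary more between cultures. Alternatives tried were a threshold of 0.01, other level filters, a doubled dispersion, the authors' adjusted p, folds centred on the median gene, calls without structural RNA and histone genes or without the sex chromosomes, and list tests on ranks or with the higher correlation. Symbols, positions and gene types are from GENCODE M 21 (GRCm38), matched by gene ID, since the tables carry no coordinates. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.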

Results

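RNA from mouse embryonic fibroblasts was sequenced as 17 libraries in 2 sets. The immortalized set holds 9 libraries, 3 for each of the genotypes +/+, +/− and −/− at Usp28, and the Ras set holds 8 libraries, 2 for each of 4 groups. In the Ras set, cells of the 3 genotypes carried activated HRas, an oncogenic small GTPase, with a GFP vector, and a group of +/+ cells carried activated HRas with a vector for USP28. Summed over the libraries of a group, depth was 11.4 to 12.4 M reads in the immortalized set and 11.4 to 13.95 M reads in the Ras set. Levels below are sums over a group in RPM, folds are log2 of the other group over +/+ as the authors' deposited tables give them, and each implied standard error (SE) comes from the dispersion of its comparison. Values for single libraries were not used here, so no spread between replicates is given for a gene.

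Usp28 (ENSMUSG00000032267, chromosome 9, 48985375 to 49042517 on the plus strand in GRCm38) encodes the deubiquitinase that the genotypes target. Its transcript was detected in every group. In the immortalized set it measured 16.5 RPM in +/+, 9.96 RPM in +/− and 13.3 RPM in the group labelled −/−, with log2 folds of -0.73 (SE 0.41, adjusted p = 0.457) and -0.32 (SE 0.29, adjusted p = 0.732). In the Ras set it fell from 26.5 RPM in +/+ to 14.8 RPM in the group labelled −/−, a log2 fold of -0.83 (95% interval -1.31 to -0.35, adjusted p = 0.00397), and the adjusted p ran from 0.00397 to 0.00871 over the alternatives except a doubled dispersion, where it was 0.0549. Ras +/− cells had 18.6 RPM (log2 fold -0.51, SE 0.24, adjusted p = 0.0905), and +/+ cells with the USP28 vector had 26.4 RPM (log2 fold -0.00, adjusted p = 1). The vector carries human USP28 by its label, so its reads need not count toward the mouse gene. The transcript shows no group to lack Usp28, so the labels are not checked by it, and directions below rest on them.

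Fbxw7 (ENSMUSG00000028086, chromosome 3, 84815268 to 84979198 on the plus strand in GRCm38) encodes the substrate-binding part of the ubiquitin ligase that the study's title names as Fbw7. It was not called in any of the 5 comparisons against +/+. Its log2 folds were 0.44 (adjusted p = 0.511) in immortalized −/−, 0.42 (adjusted p = 0.904) in immortalized +/−, -0.01 (adjusted p = 1) in Ras −/−, -0.40 (adjusted p = 0.199) in Ras +/− and 0.17 (adjusted p = 1) with USP28. The values here and for the Fbw7 substrate genes below are of RNA. Levels of the substrate proteins, which the ligase binds, were not measured.

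Immortalized −/− against +/+ cells asks what loss of Usp28 changes before transformation. Genes of the fibroblast matrix fell, among them elastin (Eln, 217 to 20.6 RPM, log2 fold -3.40, SE 0.27) and the collagen-binding proteoglycans Lum (-3.32, SE 0.34) and Dcn (-2.87, SE 0.31). Immediate-early genes, which growth signals induce within minutes, fell too, with Fos from 50.8 to 4.63 RPM (-3.46, SE 0.32, adjusted p = 1.4e-23), Ier2 at -1.92 and Egr1 from 703 to 223 RPM (-1.65, SE 0.25, adjusted p = 2.6e-08). Genes of mitosis were higher as a group, with Cenpe (1.05, SE 0.26, adjusted p = 0.00343), Cenpf (1.00, adjusted p = 0.00727) and Ect2 (0.91, adjusted p = 0.0173) among those called.

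Of 16727 genes tested, 705 were called (4.21%), 215 higher and 490 lower, with a median absolute log2 fold of 1.33. The largest falls were in Gdpd2 (47.6 to 0.958 RPM, log2 fold -5.64, SE 0.50), Cilp2 (-5.36, SE 0.62), Scara5 (-4.16), Apod (-4.10) and the Wnt inhibitor Sfrp2 (1008 to 83.6 RPM, -3.59, SE 0.25). The largest rises were in the carbonic anhydrase gene Car12 (2.47, SE 0.40), Tro (2.39), Gvin1 (2.26), the gap junction gene Gjb2 (33.0 to 149 RPM, 2.17, SE 0.26), Crabp1 (2.10) and Nipal4 (2.08).

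By list, 9 of 26 matrix genes fell and 0 rose over all genes tested, 11 lower and 2 higher adjusted over the list alone (median log2 fold -0.34, adjusted p = 1.1e-13). Cartilage markers fell in 7 of 10, the same 7 adjusted over the list alone (median -1.53, adjusted p = 1.7e-12), for example Col2a1 (224 to 71.9 RPM, -1.64) and Comp (-1.43), both named after their values were seen. Immediate-early and AP-1 genes fell in 8 of 25, or 12 lower and 1 higher adjusted over the list alone (median -0.52, adjusted p = 5.5e-12). G2/M genes rose in 4 of 24 over all genes and in 18 adjusted over the list alone (median 0.65, adjusted p = 2.9e-11). Among 21 p53 targets 3 rose, 7 adjusted over the list alone (median 0.44, adjusted p = 3.1e-06): Ccng1 (1.36, adjusted p = 1.3e-05), Pmaip1 (1.58) and Eda2r (1.38). Growth genes that Myc induces (48 tested) had a median of 0.33 with 0 called either way (adjusted p of the list 4.3e-05). Sterol synthesis genes under SREBP (25 tested, median 0.27, adjusted p = 0.00112) had 1 called by either adjustment. Contractile genes (15 tested, median 0.27, adjusted p = 0.00984) had 2 called by either adjustment, Des (2.74, SE 0.59) and Cnn1 (0.91, adjusted p = 0.0117). Neural markers had 3 of 6 higher by either adjustment (median 0.85, adjusted p = 9.9e-05) and Hox genes, which record body position, 1 higher and 2 lower of 21, with 3 lower adjusted over the list alone (median -0.31, adjusted p = 0.00424). The macrophage and leukocyte markers had a median of 0.54 over 6 tested, 1 of them called by either adjustment (adjusted p = 0.0195, or adjusted p = 0.0774 by ranks).

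Fbw7 substrate genes were not called as a list (20 tested, median 0.16, adjusted p = 0.375), and by either adjustment 1 rose, Rictor (0.87, adjusted p = 0.0282), and 1 fell, Cebpa (-1.15, adjusted p = 0.0363). Transcripts of the Fbw7 substrates Myc (0.17, adjusted p = 0.876), Jun (0.07, adjusted p = 0.964), Ccne1 (0.26, adjusted p = 0.759) and Notch1 (-0.06, adjusted p = 0.980) were not called. Interferon response genes were not called either (15 tested, 0 called by either adjustment, median -0.25, adjusted p = 0.186). The lists of Ras-MAPK output (1 of 23 higher, Il1rl1 at 0.98, with 2 higher and 1 lower adjusted over the list alone, median 0.28, adjusted p = 0.0274) and Notch targets (1 of 11 lower by either adjustment, Snai2 at -0.86, median -0.32, adjusted p = 0.0274) lost their calls at a correlation of 0.05, with adjusted p = 0.112 and adjusted p = 0.0724. The count of calls was 424 at an adjusted p under 0.01 and 285 with a doubled dispersion, under which Rictor, Cebpa, Cenpe, Cenpf, Ect2, Il1rl1, Snai2 and Cnn1 were not called. With folds centred on the median gene, which lay at 0.07, 146 genes were higher and 567 lower, and Rictor was not called, nor was Cebpa without a filter on level.

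Immortalized +/− against +/+ cells asks the same of 1 lost allele. Genes of simple and stratified epithelia and of mesothelium, the lining of body cavities, were among the largest rises. The urothelial and mesothelial plaque gene Upk1b rose from 0.566 to 383 RPM (log2 fold 9.40, SE 0.65), and the transcription factor gene Bnc1 from 0.0812 to 82.8 RPM (9.99, counting interval 7.51 to 15.3). The keratin genes Krt14 (9.80, counting interval 7.95 to 12.9) and Krt8 (8.78, counting interval 6.93 to 11.8) rose with them, and Lrrn4 went from 0 to 128 RPM, at least 526-fold higher. Matrix genes fell, with Postn from 1345 to 138 RPM (-3.28, SE 0.38), Lum at -4.91 and Eln at -3.87.

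Of 17035 genes tested, 1406 were called (8.25%), 859 higher and 547 lower, with a median absolute log2 fold of 2.14. Falls were largest in the transcription factor gene Tfap2b (42.4 to 0.241 RPM, log2 fold -7.46, counting interval -9.73 to -5.90), Bmp2 (-6.52, counting interval -9.59 to -4.66), Dio3 (-6.11, counting interval -8.37 to -4.51), Apod (-6.08, counting interval -9.11 to -4.17) and Lhx2 (-5.98, counting interval -9.01 to -4.07). Olr1, a scavenger receptor gene, rose by 9.78 (counting interval 7.30 to 15.09). The Y-linked gene Eif2s3y went from 18.7 to 0 RPM, at least 77.2-fold lower, Ddx3y fell (-2.28, adjusted p = 3.2e-06), and Xist, which silences the inactive X chromosome in female cells, rose from 89.5 to 296 RPM (1.73, SE 0.38, adjusted p = 0.000277). Sex-linked genes were thus 1 higher and 4 lower of 5 by either adjustment (adjusted p = 2.8e-10).

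Epithelial markers had 3 of 5 higher, 4 adjusted over the list alone (median 7.59, or 7.91 with members at 0 set to their bound, adjusted p = 5.9e-22). Ras-MAPK output genes had 10 of 24 higher and 1 lower, 12 and 2 adjusted over the list alone (median 0.83, adjusted p = 1.1e-05), with the feedback genes Dusp4 (4.56, SE 0.48) and Spry1 (3.02) higher and Il1rl1 lower (255 to 22.4 RPM, -3.51). Hox genes had 17 of 34 higher and 7 lower, 18 and 8 adjusted over the list alone (median 1.73, adjusted p = 1.5e-05). Among them, Hoxd13 went from 158 to 11.2 RPM (-3.82) and Hoxb2 from 0.404 to 15.2 RPM (5.24), both named after their values were seen. Among p53 targets 7 of 21 rose by either adjustment (median 0.73, adjusted p = 3e-06), with Eda2r (2.67), Pmaip1 (2.45) and Perp (2.15). Contractile genes rose in 4 of 15 by either adjustment (median 0.38, adjusted p = 3.3e-05), with Des at 7.23 (SE 0.63), Actg2 at 2.16 and Myh11 at 1.92. Matrix genes fell in 8 of 26 and rose in 1, with 8 and 2 adjusted over the list alone (median -0.52, adjusted p = 1.5e-07). Cartilage markers fell in 5 of 10 by either adjustment (median -0.91, adjusted p = 0.000355, or adjusted p = 0.0893 by ranks) and AP-1 genes in 6 of 25, 7 adjusted over the list alone (median -0.54, adjusted p = 0.000284), with Fos (-2.53), Egr2 (-1.82) and Ier2 (-1.69).

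The G2/M list had a median of -0.68 (24 tested, adjusted p = 1.5e-05) and the E2F list of S-phase genes a median of -0.51 (32 tested, adjusted p = 0.00146), with 0 members called in either list by either adjustment. Birc5 (-1.08, adjusted p = 0.0747) and Cdc45 (-1.05, adjusted p = 0.0947) had the smallest p in them. Sterol synthesis genes fell in 5 of 25 and rose in 1, 11 and 1 adjusted over the list alone (median -0.83, adjusted p = 0.000127), with Mvd at -1.41 and Idi1 at -1.40. Inflammatory and secretory genes had 6 of 17 higher and 3 lower, 9 and 3 adjusted over the list alone (median 0.94, adjusted p = 0.0067, or adjusted p = 0.0507 by ranks). Notch targets fell in 3 of 11 by either adjustment (median -0.44, adjusted p = 0.0205, or adjusted p = 0.0532 at a correlation of 0.05 and adjusted p = 0.0893 by ranks), with Hey1 at -2.40, Nrarp at -3.39 (counting interval -5.73 to -1.70) and Snai2 at -1.30. Among Fbw7 substrates (22 tested, 2 higher and 1 lower by either adjustment, adjusted p of the list 0.446), Mycn rose by 7.51 (counting interval 5.02 to 12.8), Notch4 by 2.53 (adjusted p = 0.00582), and Notch1 fell (58.6 to 25.03 RPM, -1.23, SE 0.39, adjusted p = 0.0266). Myc (0.35, adjusted p = 0.965), Jun (-0.77, adjusted p = 0.328) and Ccne1 (-0.18, adjusted p = 1) were not called. With a doubled dispersion 821 genes were called, and Notch1, Notch4, Snai2, Mvd and Idi1 were not. The error implied for a median gene is 0.40 here against 0.28 for −/−, so changes near 2-fold were rarely detectable.

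The −/− and +/− comparisons of the immortalized set shared 330 called genes, 299 of them (90.6%) in the same direction. Both lower were 223 genes, against 16.2 if the lists were independent, and both higher 76, against 7.48. Fos, Ier2, Eln, Lum and Apod were lower in both. The correlation of log2 folds across genes was 0.47, with 0.50 in simulations without any effect, and the covariance was 0.195 against 0.0766 simulated. In these simulations 0 genes were called in both comparisons, and part of the excess may come from the shared +/+ libraries, which could not be split.

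Set directly against each other, −/− and +/− immortalized cells differed in 799 of 17007 genes, 236 higher and 563 lower in −/−. G2/M genes were higher in −/− in 10 of 24, or 23 adjusted over the list alone (median log2 difference 1.37, adjusted p = 1.3e-18). Sterol synthesis genes were higher in 2 of 25, or 12 adjusted over the list alone (median 1.04, adjusted p = 7.1e-10), and the E2F list had a median of 0.55 with 0 called (adjusted p = 0.000159). Epithelial markers were lower in −/− in 4 of 5 by either adjustment (adjusted p = 1.1e-19), Hox genes in 16 of 33 with 6 higher, 19 and 7 adjusted over the list alone (adjusted p = 4.5e-09). Ras-MAPK output genes (adjusted p = 0.000469), inflammatory and secretory genes (adjusted p = 0.00136) and contractile genes (adjusted p = 0.00332) were lower as lists and sex-linked genes higher (adjusted p = 5.1e-07), of which all but the first lost their calls by ranks. The p53 targets (lower, adjusted p = 0.0355) and growth genes under Myc (higher, adjusted p = 0.0269) lost theirs at a correlation of 0.05, with adjusted p = 0.135 and adjusted p = 0.181. Coch (5.41, SE 0.50) and Hpgd (5.23, SE 0.66) were higher and Lrrn4 (-8.34, SE 0.82) lower in −/−. Usp28 (0.41, SE 0.49, adjusted p = 1.00), Jun (0.83, adjusted p = 0.561) and Notch1 (1.17, adjusted p = 0.165) were not called. With a doubled dispersion 378 genes were called.

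Ras −/− against +/+ cells asks what loss of Usp28 changes in transformed cells. Interferon response genes rose as a block. All 24 tested members rose, by either adjustment, with a median log2 fold of 3.85, or 3.95 with members at 0 set to their bound (adjusted p = 3e-52). The antiviral enzyme gene Oas2 rose from 1.16 to 83.1 RPM (6.17, SE 0.44, adjusted p = 1.7e-67), Isg15, a ubiquitin-like modifier, from 2.47 to 85.1 RPM (5.10, SE 0.34), and Oasl2 from 4.43 to 111 RPM (4.65, SE 0.29). Of 24 matrix genes 12 rose and 5 fell, with Postn from 0.529 to 300.4 RPM (9.15, SE 0.60), and the chemokine gene Cxcl5 went from 0.176 to 403 RPM (11.16, counting interval 9.31 to 14.2). Xist fell from 336 to 0.215 RPM (-10.61, counting interval -12.9 to -9.06) while Eif2s3y went from 0 to 22.4 RPM, at least 85.1-fold higher.

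Of 15868 genes tested, 4381 were called (27.6%), 2411 higher and 1970 lower, with a median absolute log2 fold of 1.06. The authors' own adjusted p, deposited for this set, was under 0.05 for 3910. The largest rises also included Rcan2 (9.93, counting interval 8.07 to 13.0), Tnn (9.56, counting interval 7.08 to 14.86), Cacna1h (9.44, counting interval 6.96 to 14.74), Cspg4 (9.23, counting interval 7.70 to 11.52) and Bmp2, which went from 0 to 170 RPM, at least 647-fold higher. Besides Xist, falls were largest in Tsix (-10.19), Dynap (-9.13, counting interval -14.44 to -6.65), Slc6a17 (-9.09, counting interval -14.40 to -6.61), Itm2a (-8.70, counting interval -14.01 to -6.21) and Slc6a15 (-8.62, counting interval -13.93 to -6.14). Tsix overlaps Xist on the opposite strand and, without strand in the libraries, its reads cannot be assigned with certainty. The Y-linked genes Kdm5d (7.15, counting interval 4.66 to 12.47) and Uty (4.05, SE 0.52) rose, as did Ddx3y (2.42, SE 0.25).

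Matrix genes had 12 of 24 higher and 5 lower, 15 and 5 adjusted over the list alone (median 0.49, adjusted p = 1.6e-05), with Dcn (0.354 to 99.8 RPM, 8.14, SE 0.71) and Col6a3 (42.0 to 438 RPM, 3.38, SE 0.22). Inflammatory and secretory genes had 7 of 14 higher and 4 lower by either adjustment (median 1.61, adjusted p = 0.000109, but adjusted p = 0.216 by ranks), with Cxcl12 higher (5.56) and Ptgs2 lower (512 to 41.1 RPM, -3.64), both named after their values were seen. Growth genes under Myc fell in 12 of 48 and rose in 1, by either adjustment (median -0.29, adjusted p = 0.0397, and adjusted p = 0.201 at a correlation of 0.05), with Slc29a2 (-1.17), Ndufaf4 (-0.96) and Mybbp1a (-0.86). The remaining lists were not called. AP-1 genes had 10 of 24 lower and 3 higher by either adjustment (adjusted p = 0.0725), with Klf4 (-1.96) and Dusp1 (-1.63) lower and Btg2 (1.62) higher. Hox genes had 7 of 17 higher and 7 lower, 7 and 9 adjusted over the list alone (adjusted p = 0.0714), and hypoxia genes 9 of 19 higher by either adjustment (adjusted p = 0.0646). The p53 targets (5 of 21 higher and 3 lower by either adjustment, adjusted p = 0.882) split, with Pmaip1 at -3.55 and Fas at 2.11, as did Ras-MAPK output genes (6 of 23 higher and 7 lower, 7 and 7 adjusted over the list alone, adjusted p = 0.837), with Mmp13 at 6.26 (counting interval 4.69 to 8.54) and Dusp5 at -2.26. Leukocyte markers were not called as a list (1 of 5 higher by either adjustment, adjusted p = 0.837), and their median level was 0.574 RPM against 66.7 RPM for the interferon genes.

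Fbw7 substrate genes were not called as a list in Ras −/− cells (2 of 19 higher and 2 lower by either adjustment, adjusted p = 0.893). Jun fell from 256 to 145 RPM (log2 fold -0.83, SE 0.21, adjusted p = 0.000731) and Klf5 by 2.02, while Notch3 rose (0.708 to 14.8 RPM, 4.39, SE 0.54, adjusted p = 2.1e-23). Myc (-0.11, adjusted p = 0.768), Ccne1 (-0.18, adjusted p = 0.605) and Notch1 (0.27, adjusted p = 0.421) were not called. With a doubled dispersion 2652 genes were called. The groups also differ in Xist and Y-linked transcripts, so they do not differ in genotype alone.

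Ras +/− against +/+ cells asks the same of 1 lost allele in transformed cells. Genes of epithelia and mesothelium were again among the large rises, such as Upk1b from 0.0878 to 557 RPM (log2 fold 12.63, counting interval 10.2 to 17.9), Upk3b from 0.264 to 677 RPM (11.33, counting interval 9.78 to 13.6) and, named after its value was seen, Krt8 from 0.263 to 465 RPM. Contractile genes fell, with the smooth muscle genes Tagln from 1129 to 73.9 RPM (-3.93, SE 0.21) and Myl9 from 126 to 1.36 RPM (-6.54, SE 0.39). Interferon response genes fell, opposite to Ras −/−, with Bst2 from 40.3 to 7.64 RPM (-2.40, SE 0.26), Oasl2 at -3.55 and Ifit1 at -2.86. The water channel gene Aqp1 went from 623 to 0.302 RPM (-11.01, SE 0.71).

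Of 15950 genes tested, 5444 were called (34.1%), 2787 higher and 2657 lower, with a median absolute log2 fold of 1.11, and the authors' own adjusted p was under 0.05 for 4983. Other large rises were in Vnn1 (11.88, counting interval 9.41 to 17.19), Ptgis (11.54, counting interval 9.70 to 14.60), Myrf (11.10, counting interval 9.56 to 13.39) and Pkhd1l1 (10.92, counting interval 8.44 to 16.23), and other large falls in Gpnmb (-10.98, counting interval -16.29 to -8.50), Hoxd13 (136 to 0.0757 RPM, -10.81, counting interval -16.1 to -8.33), Penk (-10.22, counting interval -13.27 to -8.36), Tfap2b (-9.69, counting interval -12.73 to -7.83) and Hoxa11 (-9.56, counting interval -14.86 to -7.07). Xist fell from 336 to 25.5 RPM (-3.72, SE 0.22), and Eif2s3y stood at 0.151 RPM.

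Epithelial markers rose in 5 of 6 by either adjustment (median 6.62, or 6.24 with members at 0 set to their bound, adjusted p = 1.5e-18). Contractile genes fell in 12 of 14 and rose in 1, by either adjustment (median -2.09, adjusted p = 7e-09), the exception being Mylk (4.09). Inflammatory and secretory genes rose in 11 of 16 and fell in 3, by either adjustment (median 2.47, or 2.48 with members at 0 set to their bound, adjusted p = 3.6e-09). Interferon response genes fell in 15 of 19 and rose in 1, 16 and 1 adjusted over the list alone (median -1.50, or -1.51 with members at 0 set to their bound, adjusted p = 0.000952). The other lists were not called, although many of their members were. Hox genes had 8 of 24 higher and 9 lower by either adjustment (adjusted p = 0.0515). Matrix genes had 5 of 22 higher and 11 lower, 8 and 11 adjusted over the list alone (adjusted p = 0.149), with Dcn at 8.39 and Col6a3 at -5.66. Sterol synthesis genes had 2 of 24 higher and 11 lower, 4 and 13 adjusted over the list alone (adjusted p = 0.138). Ras-MAPK output genes had 9 of 23 higher and 7 lower by either adjustment (adjusted p = 0.261), with Il1rl1 from 898 to 13.0 RPM (-6.10, SE 0.23) and Epha4 at 6.90. Among Notch targets (5 of 11 higher and 4 lower by either adjustment, adjusted p = 0.749), Hes1 rose (1.58) and Dtx4 fell (-2.63). Fbw7 substrate genes had 5 of 21 higher and 6 lower by either adjustment (adjusted p = 0.411). Jun fell from 256 to 68.4 RPM (-1.90, SE 0.21, adjusted p = 4.1e-17) and Notch1 from 31.3 to 8.71 RPM (-1.85, SE 0.26, adjusted p = 1.1e-11), and Myc rose from 161 to 245 RPM (0.61, SE 0.21, adjusted p = 0.014, or 0.0138 to 0.0302 over the other adjustments and tests and 0.129 with a doubled dispersion). Ccne1 (-0.37, adjusted p = 0.206) was not called.

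The −/− and +/− comparisons of the Ras set shared 2302 called genes, 1855 of them (80.6%) in the same direction. Both higher were 917, against 336 if independent, and both lower 938, against 339, while 188 and 259 genes moved in opposite directions, against 306 and 372. The correlation across genes was 0.48 (0.52 simulated) and the covariance 0.712 against 0.0514 simulated. In the simulations 0 genes were called in both, and part of the excess may come from the shared +/+ libraries. Directly compared, −/− and +/− Ras cells differed in 3970 of 16107 genes, 2068 higher and 1902 lower in −/−, and in 2437 with a doubled dispersion. Interferon response genes were higher in −/− in 23 of 24 by either adjustment (median log2 difference 6.25, adjusted p = 3.6e-44), contractile genes in 9 of 13 with 1 lower, 10 and 1 adjusted over the list alone (1.17, adjusted p = 7e-08), and matrix genes in 12 of 22 with 2 lower, by either adjustment (0.86, adjusted p = 1.4e-05). Epithelial markers were lower in 5 of 6 by either adjustment (adjusted p = 9.8e-12), as were endothelial markers in 3 of 5 (adjusted p = 0.014, or 0.133 by ranks). Sex-linked genes were higher in −/− in 4 of 5 and lower in 1 by either adjustment (adjusted p = 0.00777, or 0.0799 by ranks), and the estrogen-metabolizing gene Cyp1b1 had a difference of -10.93 (SE 0.53). Jun (1.08, adjusted p = 0.00207) and Notch1 (2.11, adjusted p = 2.3e-09) were higher in −/− than in +/−, whereas Usp28 (-0.33, adjusted p = 0.512) and Myc (-0.71, adjusted p = 0.0591) were not called.

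**Figure D1:**
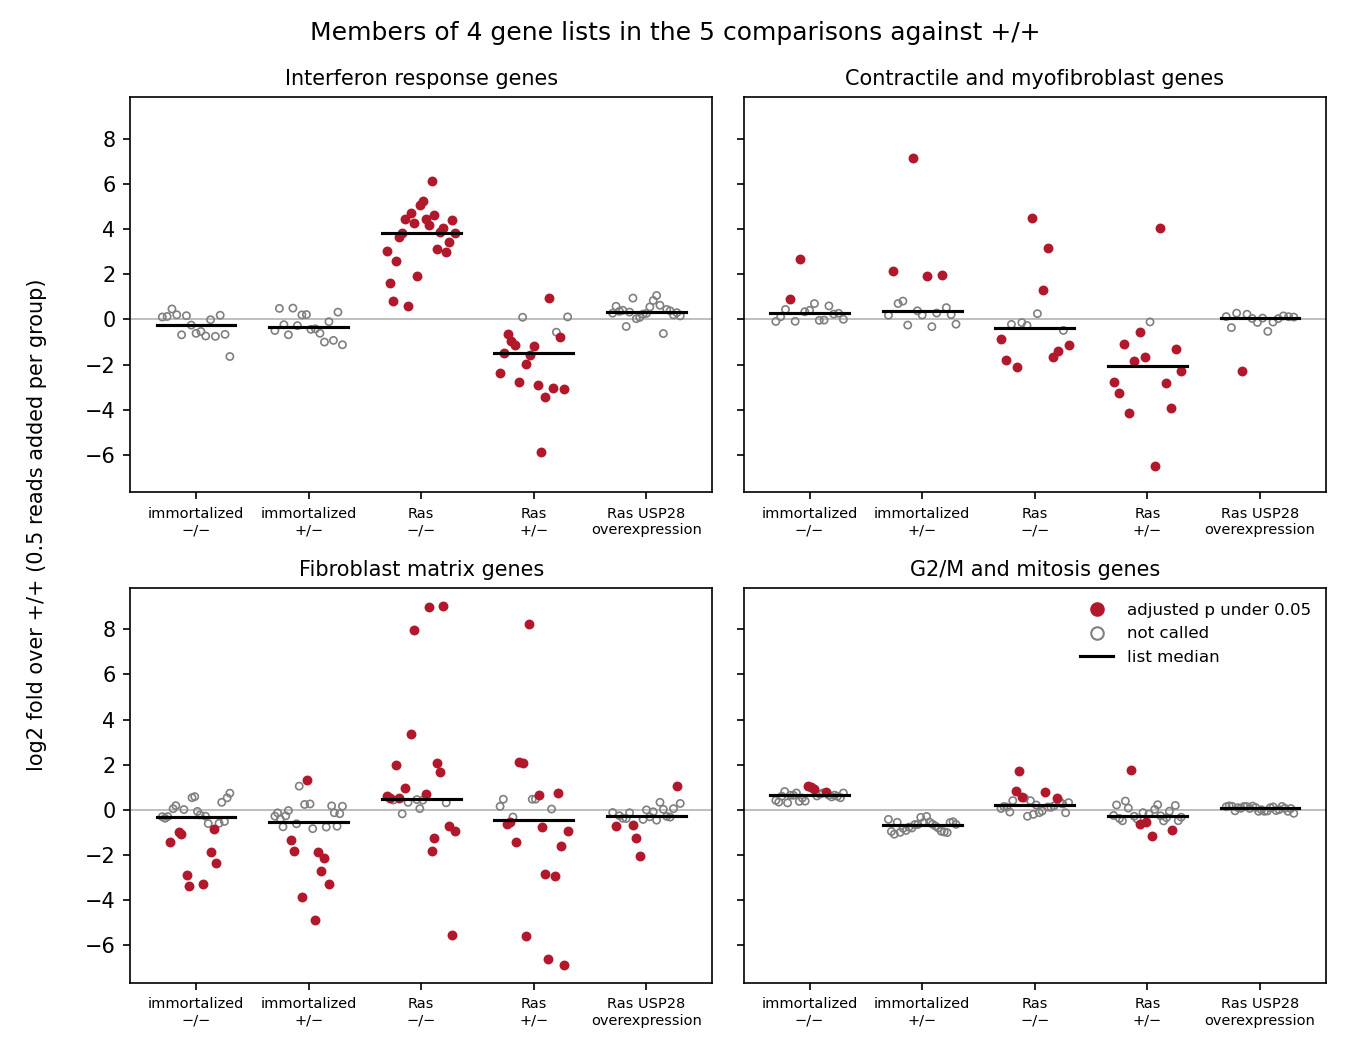
Log2 folds over +/+ (y axis, 0.5 reads added to each group) of the tested members of 4 gene lists in the 5 comparisons against +/+, with called genes filled, others open and the list median as a bar. The 24 interferon response genes all lie above 0 in Ras −/− (median 3.85), and the G2/M genes have a median of 0.65 in immortalized −/− and -0.68 in immortalized +/−.

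USP28 overexpression in Ras +/+ cells asks what more of the enzyme changes. Few genes rose. Angptl7, which encodes a secreted angiopoietin-like protein, rose from 12.8 to 64.7 RPM (log2 fold 2.34, SE 0.22, adjusted p = 3.1e-23) and the kinase gene Mtor from 59.9 to 125 RPM (1.07, SE 0.19, adjusted p = 6.7e-06). In GRCm38 Angptl7 lies within Mtor on the opposite strand (chromosome 4, 148495183 to 148500460 within 148448611 to 148557683), and without strand in the libraries the reads of the pair cannot be assigned with certainty. The collagen genes Col6a3 (41.9 to 10.1 RPM, -2.06, SE 0.23, adjusted p = 5.8e-17) and Col6a2 (-1.24, SE 0.20) fell. The largest falls were in Rpph1 (17.6 to 0.373 RPM, -5.56, SE 0.65) and Rmrp (-5.01), RNAs of RNase P and RNase MRP that carry no poly(A) tail.

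Of 15444 genes tested, 168 were called (1.09%), 14 higher and 154 lower, with a median absolute log2 fold of 2.36, and the authors' own adjusted p was under 0.05 for 155. Other falls were in n-R5-8s1, a gene of 5.8S ribosomal RNA (-4.52, SE 0.44), Il31ra (558 to 27.3 RPM, -4.35, SE 0.20), Kcnip1 (-4.30) and Htr1d (-4.29), and other rises in Arrdc4 (1.41), Gpr149 (1.14), Tmem158 (1.14), Hs3st1 (1.11) and Thbs2 (1.08). Structural RNA and replication-dependent histone genes made up 26.0% of the 154 lower loci and 1.04% of the genes tested. Matrix genes fell in 4 of 21 and rose in 1, by either adjustment (median -0.29, adjusted p = 0.000882). Neural markers fell in 1 of 7 by either adjustment (median -0.51, adjusted p = 0.00829), the one being Nes (-1.24, named after its value was seen). Lists of interferon response genes (21 tested, 0 called, 1 higher adjusted over the list alone, median 0.32, adjusted p = 0.00829) and of the unfolded protein response (15 tested, 1 lower, 3 adjusted over the list alone, median -0.18, adjusted p = 0.0399) lost their calls at a correlation of 0.05, with adjusted p = 0.0781 and adjusted p = 0.149. Myc (0.08), Jun (0.09), Ccne1 (0.17) and Notch1 (-0.38) were not called (adjusted p = 1 for each). Fbw7 substrate genes had 1 of 18 higher by either adjustment, Mtor (adjusted p of the list 0.971), and the contractile gene Cnn1 fell (-2.38, adjusted p = 0.0352). With a doubled dispersion Tmem158 and Hs3st1 were not called, and Cnn1 lost its call under every alternative in which it was tested, with adjusted p = 0.0515 to 0.192 at the threshold of 0.05.

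Of the genes called with USP28, 144 were called in Ras −/− too, 117 of them (81.2%) in the same direction, with 113 lower in both, against 19.9 if independent, and 4 higher in both, against 1.82. With Ras +/− the shared genes were 151, 122 of them (80.8%) in the same direction, with 120 lower in both against 26.9 and 2 higher in both against 1.88. The correlations across genes were 0.24 for −/− (0.53 simulated, covariance 0.0942 against 0.0430) and 0.17 for +/− (0.52 simulated, covariance 0.0774 against 0.0417). Part of the excess may come from the shared +/+ libraries. The 154 lower loci had a median log2 fold of -2.58 with USP28, of -2.27 in Ras −/− and of -1.61 in Ras +/−.

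**Figure D2:**
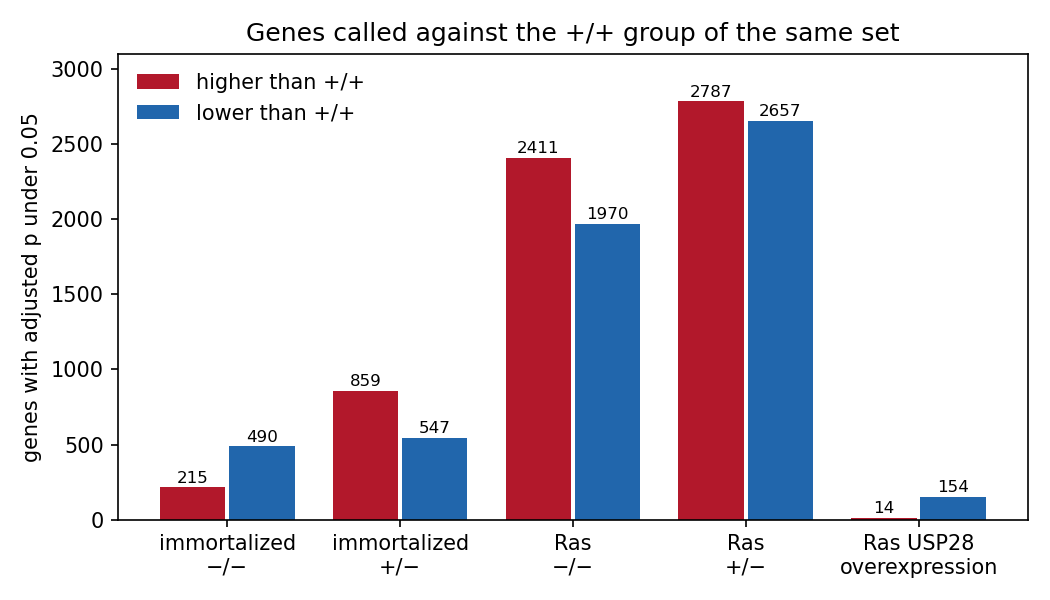
Genes called higher and lower (y axis, number of genes at an adjusted p under 0.05) in each of the 5 comparisons against +/+. The Ras genotypes have 4381 and 5444 called genes, the immortalized genotypes 705 and 1406, and USP28 overexpression 168. These counts also depend on what each comparison could detect, so they do not measure the size of the effects. In simulations, genes altered 2-fold were called in 74% and 75% of cases for Ras −/− and +/−. For immortalized −/− and +/− the shares were 52% and 8%.

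Genotype effects were also compared between the sets. Of the genes called for −/− in both sets, 347 in number, 83 (23.9%) moved the same way, and 201 were higher in Ras −/− and lower in immortalized −/−, against 54.4 if independent (correlation across genes -0.20). For +/−, 725 genes were called in both sets and 568 (78.3%) moved the same way, 399 of them higher against 106 (correlation 0.39). Over all tested genes, called or not, the shares were 42.5% for −/− and 51.2% for +/−. The +/+ libraries are not shared between the sets. The −/− effect differed between the sets in 3128 of 15068 genes, 1728 more positive and 1400 more negative in the Ras set, for example in Postn (difference 11.41, SE 0.65), Dcn (10.84, SE 0.77) and Jun (-0.89, SE 0.33, adjusted p = 0.0349). At an adjusted p under 0.01 these were 2066, and 1689 with a doubled dispersion, and with folds centred on the median gene 1948 were more positive and 1114 more negative. Xist (-10.88, SE 0.84) and Tsix (-10.51, SE 0.76) were among the most negative differences for −/−. Of 5 sex-linked genes 4 were more positive and 1 more negative, so the −/− difference is not one of genotype and Ras alone. The +/− effect differed in 2039 of 15211 genes, 1051 more positive and 988 more negative, in 1322 at 0.01 and in 1051 with a doubled dispersion. With centred folds the majority turned, to 998 more positive and 1045 more negative. Usp28 itself did not differ in either test (-0.52, adjusted p = 0.368 for −/− and 0.22, adjusted p = 0.852 for +/−).

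**Figure D3:**
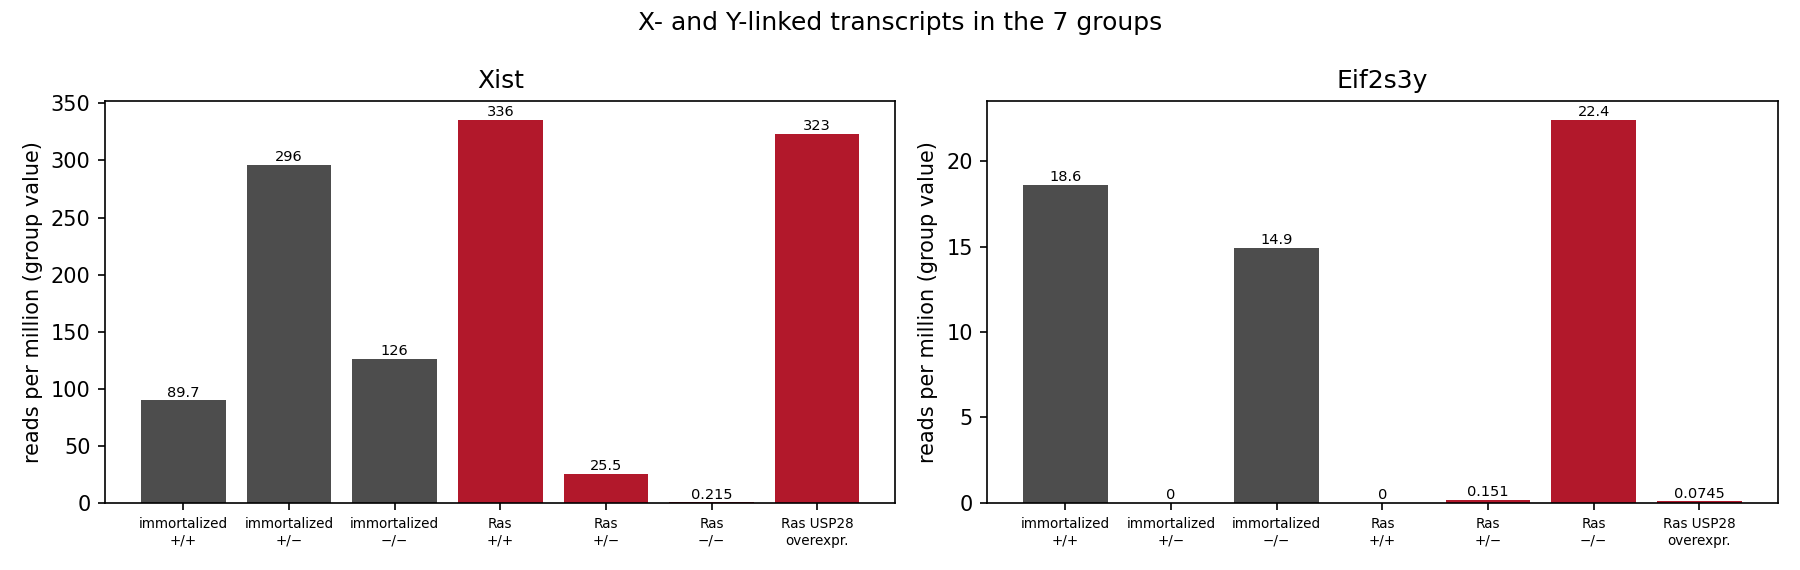
Levels of the X-linked transcript Xist and the Y-linked gene Eif2s3y (y axes, reads per group scaled to RPM) in the 7 groups, with 1 bar per group. Ras −/− has 0.215 RPM of Xist and 22.4 RPM of Eif2s3y, Ras +/+ has 336 and 0, and Ras +/+ with USP28 has 323 and 0.0745.

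Both transcripts were detected together in immortalized +/+ (Xist 89.7 RPM, Eif2s3y 18.6 RPM) and immortalized −/− (126 and 14.9 RPM), while immortalized +/− had 296 RPM of Xist and 0 of Eif2s3y. Sex-linked transcripts thus differed between +/+ and +/− in both sets and between +/+ and −/− in the Ras set. In the group with USP28, Xist was not called against Ras +/+ (log2 fold -0.06, adjusted p = 1).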

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

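The tests here were chosen only after the results were seen, except the test for genes near Usp28, which was planned before.

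The effect of the −/− genotype differed between the Ras and the immortalized set in 3128 genes, by a test of the difference of the 2 log2 folds. Sex-linked genes were 4 higher and 1 lower of 5 in it (list test, adjusted p = 0.168), so it does not compare genotype and Ras alone. Over the gene lists, the Ras effect was higher for interferon response genes (adjusted p = 2.33e-24, 14 of 15 members called higher, median difference 3.63) and matrix genes (adjusted p = 7.11e-08, 13 of 24 higher and 3 lower). It was lower for growth genes under Myc (adjusted p = 0.000183, 15 of 48 lower, median difference -0.65), with a fall in Ras −/− (adjusted p = 0.0397) that was lost at a correlation of 0.05 (adjusted p = 0.201) and a higher median in the immortalized set. Cartilage markers (higher, adjusted p = 0.0268), inflammatory and secretory genes (higher, adjusted p = 0.0386), neural markers (lower, adjusted p = 0.0421) and hypoxia genes (higher, adjusted p = 0.0488) differed too, and these 4 calls were lost at a correlation of 0.05 (adjusted p = 0.0601, 0.0962, 0.0897 and 0.175).

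The effect of the +/− genotype differed between the sets in 2039 genes. The Ras effect was lower for contractile genes (adjusted p = 2.17e-15, 12 of 14 lower, median difference -2.06) and p53 targets (adjusted p = 0.00084, 8 of 21 lower and 1 higher, median difference -0.76). Hox genes (lower, adjusted p = 0.00881), inflammatory and secretory genes (higher, adjusted p = 0.0216) and interferon response genes (lower, adjusted p = 0.0272) differed as well, and these 3 calls were lost at a correlation of 0.05 (adjusted p = 0.0923, 0.0923 and 0.115).

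The Ras genotypes differed widely, in 4381 genes for −/− and 5444 for +/−, against 168 with USP28 in the +/+ cells. Loss of Usp28 acting alike in both sets is argued against as the main source for −/−, where 23.9% of the genes called in both sets moved the same way (42.5% over all tested genes), and stays open for +/−, where 78.3% did (568 of 725, but 51.2% over all tested genes, correlation across genes 0.39). Mesothelial markers, described below, were higher in +/− of both sets, 9 of 9 tested in immortalized and 7 of 8 in Ras cells. Mesothelial cells in the +/− cultures could thus give a part of the +/− agreement, which was not tested. An excess of calls from passenger DNA around the targeted allele was neither shown nor excluded, as the share called within 10 Mb of Usp28 was above that elsewhere in all 4 comparisons, 5.95% in immortalized −/− (4.27% elsewhere, Fisher exact p = 0.252), 11.6% in immortalized +/− (8.35%, p = 0.129), 31.2% in Ras −/− (27.6%, p = 0.324) and 39.4% in Ras +/− (34.1%, p = 0.180), and with 157 to 173 tested genes near it the p of 0.05 or more set before as the bound against it was too weak to rule one out. Cultures from different embryos or body regions may account for a part, since 82.4% of the tested Hox genes were called in Ras −/− against 27.6% of other genes (Fisher exact p = 4.1e-06), as were 70.8% in Ras +/− (p = 0.000309). By their Xist and Y-linked transcripts the Ras +/+ and −/− groups do not come from the same embryos. Sex-linked transcripts also differed between +/+ and +/− in both sets. Cells of different genotypes come from different embryos, so embryo is confounded with genotype in all comparisons between genotypes, in both sets. How many calls this gives was not tested. The sex chromosomes hold 3.79% of the Ras −/− calls and 5.18% of the genes tested, too few for the bound set for them to be reached, so that test is void, and an effect of genotype that depends on transformation stays open, because each genotype of the Ras set holds 2 libraries whose embryos the labels do not name.

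Interferon response genes were higher in Ras −/− than in +/+, all 24 of those tested. Leukocytes among the cells are argued against by the median level of 14 leukocyte markers, 0.574 RPM in Ras −/−, where the interferon genes had a median of 66.7 RPM, and by Lyz2, at 0.215 RPM, although Cd14 rose from 1.59 to 3.87 RPM, Fcer1g stood at 0.352 RPM in +/+ and 1.08 RPM in −/−, and Csf1r at 8.96 and 9.10 RPM. A doubled dispersion between libraries is argued against as the source, since 22 of the 24 were still called with it, while a still larger spread stays open. Loss of Usp28 acting alike in both sets is argued against as the whole cause by the test of the difference (adjusted p = 2.33e-24), but not excluded. That test rests on the common dispersion of each comparison, and a difference between cultures in either set could also give its result. An interferon response in the culture of a single embryo or library, or one that needs both Ras and loss of Usp28, could each give the pattern, and values for single libraries, which would bear on the first, were not used here.

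Lower loci with USP28 in the Ras set, 154 in number, were lower in Ras −/− as well (median log2 fold -2.27), where no USP28 vector was present, so an effect of the vector on these loci is argued against as the whole cause. A higher share of RNA without poly(A) tails in the Ras +/+ libraries may account for a part, as 40 of the 154 are structural RNA or histone genes (Fisher exact p = 1.3e-45) and 13 loci overlap an annotated structural RNA gene. Over all 160 tested genes of these classes the median was -0.84 in Ras −/− and -0.74 in Ras +/−, both between the bounds set for and against, and -0.34 with USP28, for which no bound was set, so this source and a difference in the cells cannot be told apart for the loci. The 114 loci outside these classes were lower in the Ras genotypes too, with medians of -2.27 in −/− and -1.56 in +/−. All 3 comparisons share the same 2 libraries of Ras +/+, which alone can give the common direction.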

How the results depend on the processing

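Tests with a doubled dispersion, the approximate test, the authors' adjusted p, centred folds, calls without structural RNA and histone genes or without the sex chromosomes, and list tests on ranks or at a correlation of 0.05 were chosen only after the results were seen. No paired analysis was possible because each table holds 1 value per comparison and none per replicate. For the same reason other normalizations, other tools, pseudocounts, fits of 2 groups or of all 17 libraries, each library left out in turn, an estimated correlation and other splits of the libraries were not run, and the Ras set was not tested against the immortalized set.

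Among 266 pairs of a named gene and a comparison, no direction turned under any alternative run. The alternatives reuse the deposited log2 ratios, apart from the small count added in the approximate tests, and only centring shifts the folds. The directions were thus largely fixed in advance, and their constancy is no evidence of robustness. Of the outcomes, 1692 kept their side of the threshold, 41 lost and 1 (Mmp3) gained a call. Of the losses, 22 came with a doubled dispersion and 12 at 0.01. With a doubled dispersion 285 genes were called in immortalized −/−, 821 in immortalized +/−, 2652 in Ras −/−, 378 and 2437 between −/− and +/− of the immortalized and the Ras set, and 1689 and 1051 in the tests between sets for −/− and +/−; Usp28 in Ras −/− then had an adjusted p of 0.0549. The larger error of this setting lowers such counts by construction. At an adjusted p under 0.01 the counts were 424 for immortalized −/−, 2066 and 1322 between the sets. Lists called with USP28 were 8 by ranks and 2 at a correlation of 0.05, between the sets 3 and 3 for −/− and 8 and 2 for +/−; the cause was not tested.

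The share moving the same way over all tested genes, called or not, was 65.9% and 63.7% for −/− with +/− (immortalized, Ras), 54.3% and 57.7% for USP28 with −/− and +/−, and 42.5% and 51.2% between sets for −/− and +/−. Among the genes called for +/− in both sets the share was 78.3% of 725 and, at an adjusted p under 0.01, 81.8% of 523. Simulations with no effect and a common +/+ group gave 66.8% and 67.1% for −/− with +/− and 67.4% and 67.1% for USP28 with −/− and +/−. The 4 shares with a common +/+ group do not exceed these, so they are no evidence of agreement. They do not show its absence either, because the simulations hold no altered gene. The covariances of log2 folds of the same 4 pairs were above their simulated values, and the shared +/+ libraries may give a part of that excess. Of the values that answer a comparison, 143 stayed within their bounds, 23 moved and 1 lost its call. Depth limits genes near 1 RPM, where a group holds about 12 reads.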

Other observations

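All tests in this part were chosen only after the results were seen.

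A set of genes marks mesothelium, the lining of body cavities, and many of them rose in +/− cells. In immortalized +/− cells Wt1 went from 0.243 to 58.3 RPM, Upk3b from 1.95 to 508 RPM (log2 fold 8.03, implied SE 0.48) and Krt18 from 0.162 to 39.0 RPM. In Ras +/− cells Gpm6a went from 0.263 to 94.2 RPM and Wt1 from 0.0882 to 124 RPM. In Ras −/− cells the epithelial keratin gene Krt19 went the other way, from 71.5 to 0.215 RPM. These genes were named after their values were seen.

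Mesothelial cells in the immortalized +/− cultures are a candidate source of these transcripts. The test took 11 further markers of mesothelium, none of them among the genes that raised the question. Their median log2 fold was 2.90 in immortalized +/−, above all of 10000 random lists matched on level, and all 9 tested members were called higher. Calb2, also among the 11, was not tested, at 0 RPM in +/+ and 0.0808 RPM in +/−. Gata5 (0 to 2.46 RPM) and Podxl (0.749 to 5.79 RPM) passed the filter on level only through +/−. The filter thus sets a part of the count of members called. Msln was among the most abundant, from 21.2 to 476 RPM (4.49, SE 0.39), with Ezr from 46.3 to 432 RPM and Krt7 from 2.75 to 91.2 RPM. The same markers had a median of 3.47 in Ras +/−, where 7 of 8 were higher and Msln lower (-1.02), and medians of -0.73 in immortalized −/− and -1.56 in Ras −/−. Of the 11 markers 7 measured at least 1 RPM in immortalized +/+ cells as well and 0 are in another list used here. Several of these genes are also expressed by other epithelia, and the labels name no sort or gate that would remove such cells.

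Some abundant loci varied between the groups of the Ras set. Lars2 stood at 3519 RPM in Ras +/+, 1197 RPM in +/− and 275 RPM in −/−. Rn7sk, an RNA without a poly(A) tail, stood at 27.2 RPM in +/+, 7.54 RPM in +/− (log2 fold -1.85, SE 0.26) and 1.58 RPM in −/− (log2 fold -4.11, SE 0.38). In the immortalized set Lars2 measured 101 RPM in both +/+ and −/− (log2 fold -0.01, adjusted p = 1). In immortalized +/− it stood at 60.7 RPM (log2 fold -0.74, SE 0.39, adjusted p = 0.370), which was not called.

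The cell cycle inhibitor gene Cdkn2a, whose alternative product p19ARF the hairpin targets, measured 119 RPM in immortalized +/+ and 117 RPM in −/− (log2 fold -0.02, adjusted p = 1). It stood at 221 RPM in immortalized +/− (0.89, adjusted p = 0.185), which was not called, and rose in Ras +/− from 12.9 to 56.8 RPM (2.13, SE 0.24, adjusted p = 7.8e-17). In Ras −/− it had 12.7 RPM (-0.03, adjusted p = 0.977).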
